A study of Mus musculus with 16 samples.

How the data were processed

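GFP-positive photoreceptors sorted from mouse retinal organoids were profiled in 16 libraries, and 3 deposited tables were used. Reads were trimmed with Trimmomatic 0.36 and quantified with kallisto 0.42.5 against the Ensembl cDNA sequences of GRCm38.p4, per the submitters' processing notes and the series design text. Gene values were made by the authors with tximport, scaled by transcript length, and turned into CPM with edgeR, per the design text.

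The deposited gene table of 32166 genes is named as CPM, but its values run from -1 to 198.2. They equal the square of log2(CPM + 1) minus 1: of 8688 genes with transcripts and CPM above 0 in all 16 libraries, 8488 (97.7%) had a constant ratio of back-transformed CPM to deposited TPM across libraries, at a tolerance of 0.0001 on the log2 ratio. Back-transformed CPM was used, and its columns sum to between 642418 and 885155. The shares of genes at -1, that is at 0 CPM, were 40.0 to 49.3% per library. The deposited tables of estimated counts and of TPM per transcript stop at 65535 transcripts, of which 65096 (99.3%) matched a GENCODE annotation of GRCm38. The deposited TPM of the transcripts held sums to between 637515 and 690714 per library. Sums of the deposited estimated counts are therefore complete for 11084 genes, and Nrl, Crx, Gnat1 and Gnat2 are not among them. Library totals were rebuilt from the ratios of the tables. All columns of the tables were mapped to samples by name.

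The test fixed before the data were examined was edgeR's quasi-likelihood test on gene sums of estimated counts rounded to whole numbers. Because those sums are incomplete and the gene table holds transformed CPM, the reported test is limma with trend, listed among the alternatives before the data were examined, on log2(CPM + 1), for 15202 genes with a CPM of at least 1 in at least 2 libraries. The choice was made on the coverage of the tables before any count of called genes was seen. The edgeR test (9318 genes with at least 10 counts in at least 2 libraries) is given beside each count of the planned comparisons, and contrasts added later have limma alone. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Day contrasts used source and day as factors over all 16 libraries, the ESC day 21 contrast 1 mean per group, the source contrast day and source, and the slope contrast source, day as a number and their product. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

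Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry on log2(CPM + 1). The planned input was instead voom log2 CPM of the gene sums, on which camera was run with the preset correlation as an alternative. The 34 lists were fixed before the data were examined. Named genes followed a rule fixed at the same time: landmark photoreceptor genes whatever their test; the 8 largest rises and falls among called genes with a mean CPM of at least 5 for day 35, the source contrast and the ESC contrast, and 4 for the others, without predicted gene models; up to 4 called members of each list described, or up to 2 of the highest level where none was called; and the sex chromosome and imprinted genes in the source contrast. Some genes that this rule gives are not reported here.

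Library totals of 3863994 to 21889920 estimated counts set the precision of low genes. The fits were tested on simulated counts for 15149 genes with 200 changed, drawn from genes with a mean CPM of at least 5. Recovery of lower genes was not simulated. For day 35 against day 18, limma recovered 11% of genes changed 2-fold and 52% of those changed 4-fold, with 3 unchanged genes called. For the source contrast the shares were 58% and 94%, with 7 unchanged genes called. In the day 35 simulation DESeq2 called 56 unchanged genes and recovered 29% and 77%. Simulated genes varied independently and, apart from the set changes, had the same mean in all libraries. In the real data genes of a list moved together and some day 18 libraries stood apart. These shares may therefore not hold for the real data.

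Alternatives were DESeq2, other size factors, no filter or a stricter one, counts rebuilt by length and a pseudocount of 0.1. Others were a replicate block, each library left out, and contrasts within each source. The within-source contrasts came from a model of 1 mean per group, with the spread pooled over all 16 libraries. Chosen after seeing the data were the removal of the day 18 libraries labelled ESC 1 and iPSC 1 (low Nrl), the removal of those labelled ESC 1 and iPSC 2 (Y-linked genes), CPM rescaled to the same sum in each library, and limma array weights, which weight each library by its fit. All libraries stayed in the groups their labels give. Regroupings were drawn up to 100 times.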

Results

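Retinal organoids, three-dimensional cultures that form retinal tissue from pluripotent stem cells, were grown from mouse embryonic stem cells (ESCs) and from induced pluripotent stem cells (iPSCs), both carrying a green fluorescent protein driven by the promoter of Nrl, a transcription factor required for rod fate. GFP-positive cells were sorted at days 18, 21, 25, 28 and 35 and profiled by polyA RNA-seq. The 16 libraries comprised 9 from ESCs and 7 from iPSCs. Day 18 had 3 ESC and 2 iPSC libraries, day 21 had 3 and 1, day 25 had 1 and 2, and days 28 and 35 had 1 of each source. The library totals rebuilt from the deposited tables ranged from 3863994 estimated counts in iPSC day 28 to 21889920 in iPSC day 18 replicate 2. A single estimated count was then worth 0.213 and 0.037 on the scale of the normalized gene values (CPM). The labels do not say whether libraries of one group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Genes at days 28 and 35 were tested with the spread pooled over all libraries.

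The day 18 libraries were not alike. The library labelled ESC day 18 replicate 1 and that labelled iPSC day 18 replicate 1 held Nrl at 17.74 and 15.99 CPM, against 135.8 to 881.3 CPM in the other day 18 libraries, and both held the proliferation antigen Mki67 at 406.1 and 462.5 CPM. Across genes, the log2 levels of this pair correlated at 0.992, the highest of the 120 pairs of libraries. The next pair, ESC day 21 replicate 2 with iPSC day 21, reached 0.984, and pairs within a group ranged from 0.896 to 0.957, below several pairs from different groups. Genes are not independent replicates, and these correlations describe the libraries only. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 8.7. Libraries of the same RNA or culture can exceed that noise too, and each library was counted as 1 sample because the labels list it as one. The first principal component held 45.6% of the variance and the second 17.5%.

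The comparison of day 35 with day 18 asked how the sorted cells changed over the whole time course. Genes of the rod light response were among the largest rises. Gnat1, the rod transducin subunit, went from 4.37 ± 1.45 CPM (SD, n = 5) at day 18 to 193.7 ± 76.8 CPM (n = 2) at day 35 (log2 fold change 5.09 on the log2(CPM + 1) scale, adjusted p = 0.00053), and Pde6a, a subunit of the rod phosphodiesterase, from 0.669 ± 0.869 to 176.2 ± 70.4 CPM (6.76, adjusted p = 1.5e-05). Further large rises were in the rod channel subunits Cnga1 (6.83) and Cngb1 (6.58), in Pde6g (6.68), in the calcium sensor recoverin Rcvrn (6.67) and the outer segment retinol dehydrogenase Rdh8 (5.78). The largest falls were in Fgf15 (-6.16), Cyp26b1 (-5.10), Foxn4 (-4.78), Islr2 (-4.73), Nnat (-4.63), Mki67 (-4.41), Sfrp2 (-4.30) and Cyp26a1 (-4.14). Gnat1 lies on chromosome 9 at 107674474 to 107679712, Nrl on chromosome 14 at 55518978 to 55524981 and Fgf15 on chromosome 7 at 144896531 to 144900953 in GRCm38, all annotated as protein-coding genes.

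**Figure D1:**
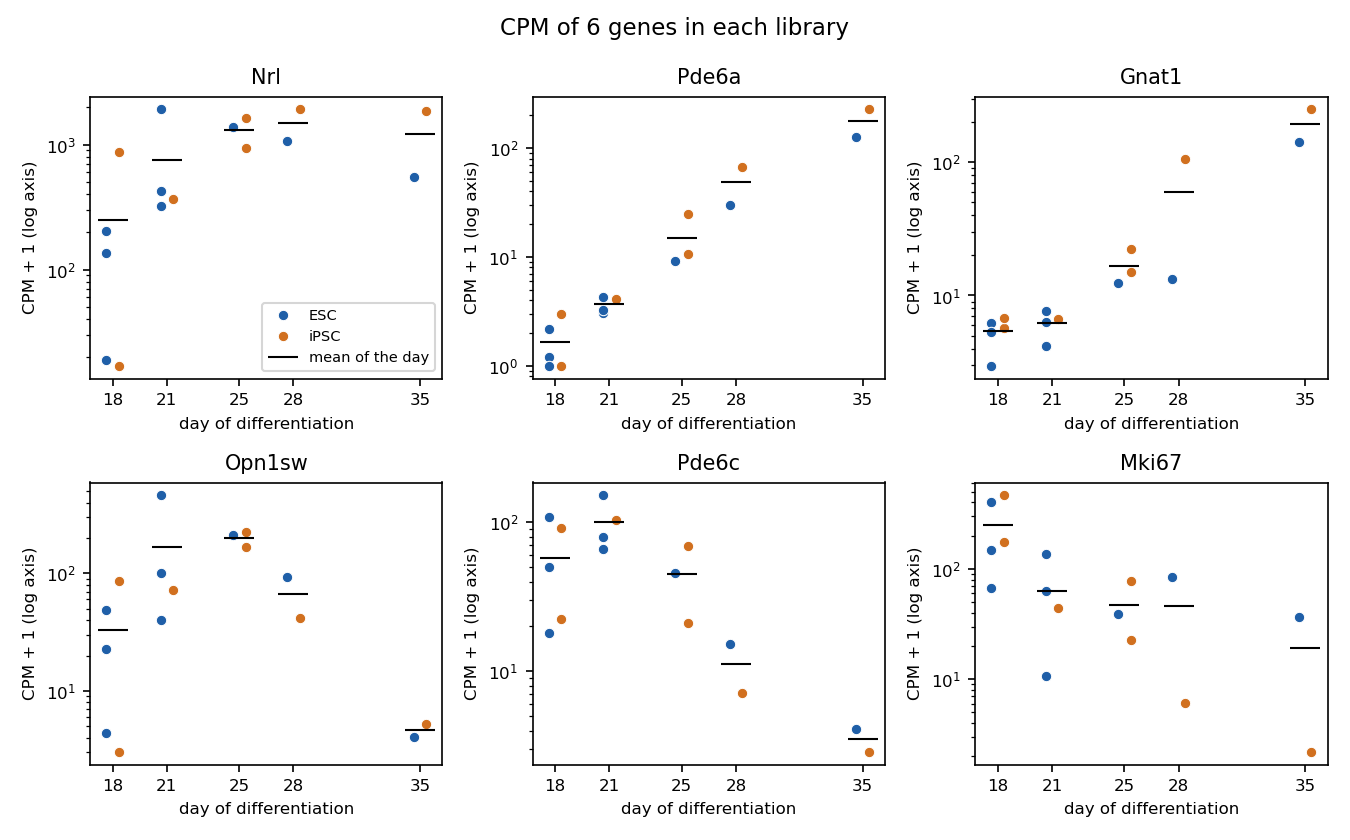
CPM + 1 on a log axis against the day of differentiation for 6 genes, with 1 point per library, ESC in blue, iPSC in orange and a bar at the mean of each day. Gnat1 lay between 139.4 and 247.9 CPM at day 35 and at or below 5.7 CPM at day 18, while Opn1sw lay at 3.1 and 4.2 CPM at day 35.

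In total 1144 of 15202 genes were called between day 35 and day 18, 690 higher and 454 lower (limma with trend, Benjamini-Hochberg adjusted p under 0.05). The edgeR quasi-likelihood test on gene sums, restricted to the 9318 genes with complete transcripts and enough counts, called 643, with 397 higher and 246 lower. The count moved with the libraries kept. Without the pair of day 18 libraries with low Nrl, 147 genes were called, 107 higher and 40 lower, a setting chosen after seeing the data. That setting also leaves fewer day 18 libraries, so the fall in calls cannot be put down to the pair alone. Leaving out iPSC day 35 gave 295 calls, iPSC day 18 replicate 1 gave 354, ESC day 18 replicate 1 gave 512, ESC day 18 replicate 3 gave 742, and ESC day 18 replicate 2 gave 1808. Every one of the 1144 genes kept its direction without the low-Nrl pair, and 144 kept their call. The genes were picked in a fit that shares the remaining libraries, so kept directions are no independent support.

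Of the landmark genes, Prph2, a structural protein of the outer segment disc, rose (4.65, adjusted p = 0.042), as did Gnat1. Nrl (3.38, adjusted p = 0.11), Crx (1.32, 0.29), Nr2e3 (3.37, 0.135), Pde6b (5.55, 0.061) and Sag (4.13, 0.077) did not pass. The cone genes Opn1sw (-1.81, adjusted p = 0.35), Arr3 (0.32, 0.81) and Gnat2 (-0.87, 0.47) did not pass, and Opn1mw was listed at 0 in every library. Day 18 levels of Nrl were 250.7 ± 361.4 CPM (n = 5), and the SD exceeded the mean.

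The rod phototransduction list held 19 measured genes, of which 14 rose and none fell, or 19 adjusted over the list alone. They included Pde6a, Gnat1, Rcvrn and the guanylate cyclase Gucy2f (4.18). Of the outer segment and photoreceptor cilium list, 17 of 28 rose, or 28 adjusted over the list alone, among them Wdr17 (3.93), Rdh8, the potassium channel Kcnv2 (4.70) and Prom1 (2.71), the disc protein prominin. Of the ribbon synapse list, 8 of 23 rose, or 19 adjusted over the list alone, with Cplx4 (4.92), the calcium channel Cacna1f (5.03), Cabp4 (3.41) and Lrit1 (4.55). Among transcription factors of photoreceptors, Esrrb (4.16) and Casz1 (1.87) rose and the other 12 of 14 did not pass. Without the low-Nrl pair, 6 of the phototransduction genes, 3 of the outer segment genes and 2 of the synapse genes were called, and the medians of the lists were 3.83, 2.10 and 1.11 in place of 4.45, 3.29 and 1.91. Of the transcription factors, 1 was called without that pair.

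Some genes of dividing and immature cells fell. In the cell cycle list (adjusted p = 0.39 by camera with an estimated correlation), 12 of 32 genes fell and none rose, or 30 adjusted over the list alone, with Mcm2 (-2.45), Birc5 (-2.66), Mcm7 (-1.46) and Mcm3 (-3.18). In the retinal progenitor list (0.39 in the same test; fry, 0.066), 6 of 22 fell, or 15 adjusted over the list alone, with Sfrp2, Dll1 (-2.94) and Fgf15. In the list of ribosomal proteins, used as a check of RNA composition, 15 of 27 fell and none rose, or 25 adjusted over the list alone, with Rpl3 (-1.53), Rpl32 (-1.44), Rps4x (-1.22) and Rplp0 (-1.79). Rpl3 stood at 558.5 ± 140.1 CPM at day 18 and 201.0 ± 89.2 CPM at day 35. Cyp26b1 and Cyp26a1, which break down retinoic acid, were the called members of the 15 retinoic acid response genes, with 5 falling adjusted over the list alone. Retinoic acid was in the culture medium for part of the course per the labels, and Cyp26a1 stood at 45.5 ± 24.2 CPM at day 18 and 1.39 ± 1.44 CPM at day 35. Without the low-Nrl pair, 1 retinoic acid response gene was called and no gene of the cell cycle, progenitor or ribosomal lists, where the medians were -1.98, -1.81 and -0.98 in place of -2.63, -2.40 and -1.01.

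Other groups moved in part. In the list of photoreceptor and glial injury genes, 6 of 14 rose, or 7 adjusted over the list alone, among them Lcn2 (1.79), Stat3 (1.66), Edn2 (2.11) and Serpina3n (3.47). Of the chromatin and nuclear architecture list, 5 of 11 fell, with Hmgb2 (-2.42), Lmnb1 (-1.32), H1f0 (-1.39) and Cbx5 (-1.12). The imprinted genes went both ways, with Zrsr1 (2.14) and Impact (0.92) rising and Nnat, Cdkn1c (-1.98) and 1 further gene falling. Hk1 (2.78) rose and P4ha1 (-0.92) fell in the glycolysis and hypoxia list, Ndufa4 (1.07) rose in the oxidative phosphorylation list, Acat2 (-1.30) and Nsdhl (-0.72) fell in the cholesterol list, and Atf3 (1.74) and Atf4 (1.01) rose in the stress response list. Among markers of other cell types, the bipolar genes Prkca (1.99), Grm6 (3.57) and Scgn (2.41) and the Müller glia genes Abca8a (2.61) and Aqp4 (3.86) rose, and the horizontal cell factor Onecut1 (-3.35) and the cone gene Pde6c (-3.71) fell. Cryab (1.90) of the lens list rose too. Without the low-Nrl pair, 2 injury genes, 2 imprinted genes, 1 bipolar gene, 1 horizontal gene and 1 cone gene were called, and 0 in the chromatin, glycolysis, oxidative phosphorylation, cholesterol, stress response, Müller glia and lens lists. Medians did not all shrink with the calls: they were 1.06 in place of 0.85 for Müller glia, 0.25 in place of 0.25 for stress response and 1.30 in place of 1.36 for injury. Grm6 was at 78.8 CPM in ESC day 35 and 1.2 CPM in iPSC day 35, and Aqp4 was at 222.1 and 5.7 CPM. The mean log2 level of the stress response list was 5.79 in ESC day 35 and 6.49 in iPSC day 35, against 5.51 to 5.86 at day 18. For oxidative phosphorylation it was 6.27 and 6.73, against 5.89 to 6.3 at day 18.

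Camera with a preset correlation of 0.01 called 15 of the 34 lists at day 35 and none with an estimated correlation, where the smallest adjusted p was 0.29. The estimated correlation ran from -0.32 for lens to 0.86 for cell cycle, with 0.8 for outer segment and 0.68 for rod phototransduction. For lists far above the preset value, camera with 0.01 can call too readily, here and in the other comparisons. Fry, which asks whether the genes of a list move one way and not whether they differ from other genes, called 9, among them rod phototransduction (adjusted p = 0.0036), outer segment (0.016), cell cycle (0.044), ribosomal proteins (0.01), ribbon synapse (0.026), retinoic acid response (0.016), the injury list (0.0036), horizontal cells (0.044) and lens (0.026). The lens list held 3 measured genes, of which 1 was called, and camera gave it an adjusted p of 0.48.

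**Figure D2:**
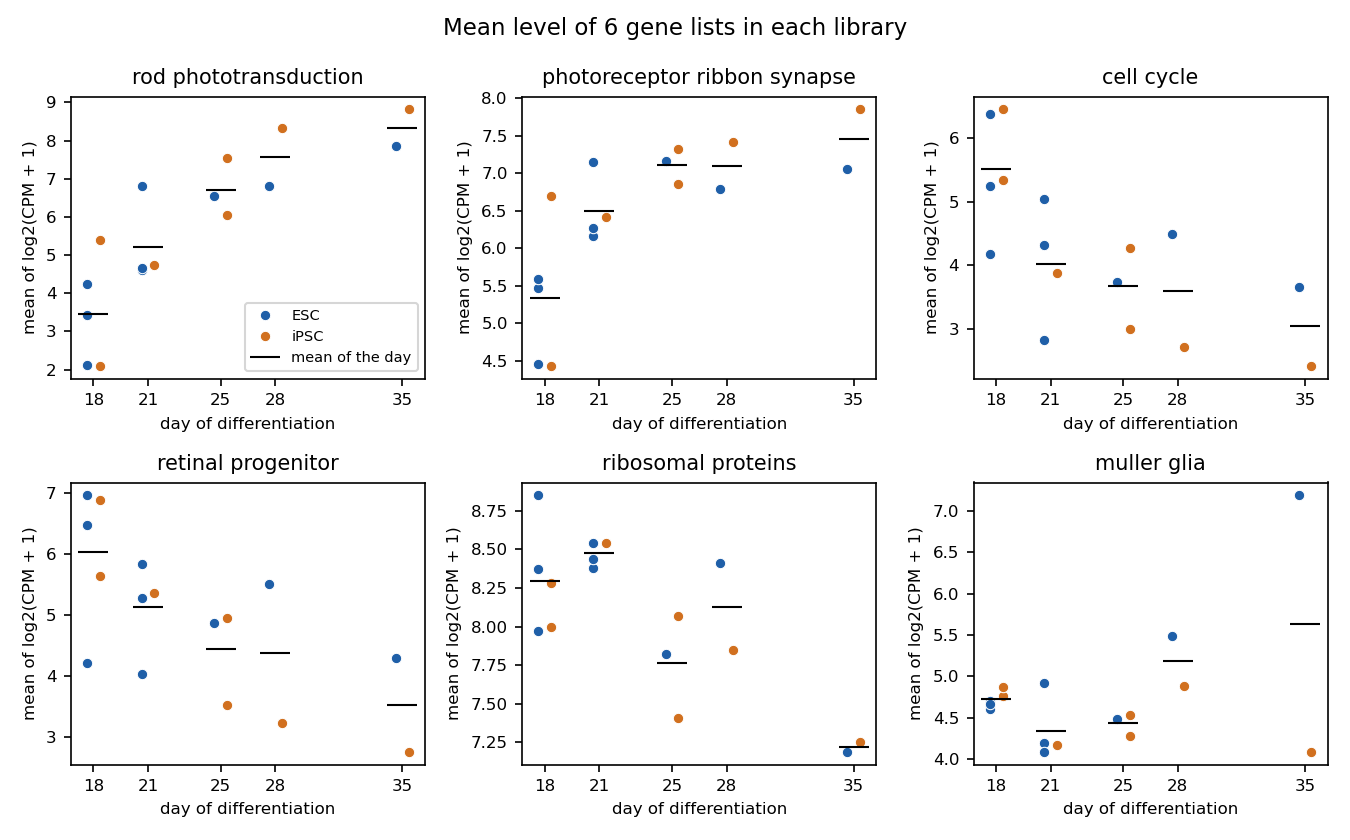
Mean of log2(CPM + 1) over the members of 6 gene lists against the day of differentiation, with 1 point per library, ESC in blue, iPSC in orange and a bar at the mean of each day. All 19 phototransduction genes had positive fold changes at day 35, and the Müller glia list was highest in the ESC day 35 library.

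At day 28, 88 genes were called against day 18, 77 higher and 11 lower, and edgeR on gene sums called 37, all higher. Pde6g (6.14), Rdh8 (5.65) and Rcvrn (5.59) were among the largest rises, and Cyp26a1 (-4.16), Xkr7 (-2.26) and the planar polarity gene Vangl2 (-1.81) among the largest falls. Of 19 phototransduction genes, 6 rose, or 18 adjusted over the list alone, among them Pde6a (4.85), Gnat1 (2.77) and Gngt1 (4.71). Wdr17 (3.24), Rdh8 and Kcnv2 (4.47) of the outer segment and photoreceptor cilium list rose, as did Cplx4 (3.67) of the ribbon synapse list. The imprinted Zrsr1 (1.32) rose too, and Nsdhl (-1.03) of cholesterol synthesis fell. Nrl (3.88, adjusted p = 0.13) and Opn1sw (1.94, adjusted p = 0.33) did not pass. Camera called 13 lists with the preset correlation, fry called rod phototransduction (adjusted p = 0.036) and no other list, and camera called none with an estimated correlation (smallest adjusted p = 0.53). Without the low-Nrl pair 1 gene, Pde6a, was called. Leaving out 1 library left 7, 203 or 9 calls for ESC day 18 replicates 1, 2 and 3, 11, 8 or 152 for ESC day 21 replicates 1, 2 and 3, and 10, 5 or 146 for ESC days 25, 28 and 35. It left 4 or 539 for iPSC day 18 replicates 1 and 2, 13 for iPSC day 21, 14 for iPSC day 25 replicate 2, and 1 or 146 for iPSC days 28 and 35. Named after their values were seen, the 4 were Ckmt1, Pde6a, Wdr17 and Xrra1, the 5 Ckmt1, Gm13051, Gnat1, Pde6a and Wdr17, and the 1 Gm10288.

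At day 25, 6 genes were called, all higher, and edgeR called 7. The 4 of the named-gene rule were Rnf207 (3.81, adjusted p = 0.037), Pde6a (3.00, adjusted p = 0.035), Rasgef1a (2.82) and the diacylglycerol kinase Dgkk (2.66). Nr2e3 stood at 1369 ± 329 CPM (n = 3; log2 fold change 4.41, adjusted p = 0.09), Nrl at 1319 ± 354 CPM (3.66, adjusted p = 0.1) and Opn1sw at 200.6 ± 30.4 CPM (3.68, adjusted p = 0.091). At an unadjusted p under 0.05, 3707 genes passed. Lrrc27 and Tub, outside the rule and named after their values were seen, were the other called genes. Without the low-Nrl pair 0 genes were called. Leaving out 1 library gave 1005 calls for iPSC day 18 replicate 2, 356 for iPSC day 25 replicate 1, 32 for ESC day 18 replicate 2, 26 and 25 for ESC and iPSC day 35, 15 and 10 for ESC day 21 replicates 3 and 1, and 3 (Dgkk, Pde6a and Tub) for ESC or iPSC day 28. It gave 0 for ESC day 18 replicate 1 or 3, ESC day 21 replicate 2, ESC day 25, iPSC day 18 replicate 1, iPSC day 21 and iPSC day 25 replicate 2.

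At day 21 no gene was called by limma or edgeR, with 2854 and 1610 genes at an unadjusted p under 0.05, while DESeq2 called 107. The log2 fold changes of Nrl (2.61), Crx (1.63), Nr2e3 (3.22), Prph2 (2.72), Opn1sw (2.66) and Neurod1 (1.69), a factor of photoreceptor differentiation, were positive and that of Mki67 (-2.28) negative, none past the threshold. Adjusted over the list alone, 20 of 28 outer segment genes were higher and 19 of 32 cell cycle genes lower, and their medians were 0.79 and -1.03 without the low-Nrl pair in place of 1.81 and -1.62. Camera called 15 lists with the preset correlation, none with an estimated correlation (smallest adjusted p = 0.5), and fry called none. Leaving out iPSC day 18 replicate 2 gave 249 calls, and leaving out ESC day 21 replicate 1 gave 5, namely Cyp26a1, Dgkk, Gm8430, Svip and Zfp365, some outside the rule and named after their values were seen.

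Between ESC day 21 and ESC day 18, the only groups with 3 libraries each, no gene was called by limma (2070 genes at an unadjusted p under 0.05) or edgeR (991), and DESeq2 called 2, Enpp4 and Fbxl21, named after their values were seen. Nrl (log2 fold change 2.99, SE 1.40, adjusted p = 0.37), Crx (1.72), Nr2e3 (3.66) and Prph2 (2.82) had positive values that did not pass. Leaving out ESC day 21 replicate 2 gave 2 calls, the predicted genes Gm10359 and Gm12671. Camera called 16 lists with the preset correlation, 9 without ESC day 18 replicate 1, 10 without the low-Nrl pair, and none with an estimated correlation (smallest adjusted p = 0.54), and fry called none.

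The comparison of sources asked whether iPSC-derived and ESC-derived cells differed once day was accounted for. No gene was called by limma (840 at an unadjusted p under 0.05), edgeR (318) or DESeq2, and the smallest adjusted p was 0.753. The half-width of the 95% confidence interval had a median of 0.45 on the log2 scale. Levels over all days were 671 ± 648 CPM in ESC (n = 9) and 1087 ± 743 CPM in iPSC (n = 7) for Nrl, whose log2 difference, iPSC minus ESC, was 0.36 with an interval of -1.32 to 2.04. The interval was 0.14 to 1.48 for Gnat1 (0.81), at an adjusted p over 0.75. Crx (0.21), Nr2e3 (0.49), Pde6b (0.21), Prph2 (0.27) and Arr3 (0.05) were positive, and Sag (-0.11), Opn1sw (-0.31) and Gnat2 (-0.22) negative. Nrl, Crx, Nr2e3, Pde6b and Prph2 turned negative without ESC day 18 replicate 1 and iPSC day 18 replicate 2, a setting chosen after seeing the data.

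Of all genes tested, the Y-linked Eif2s3y (-3.84) and Ddx3y (-2.96) had the lowest values, and the Y-linked Uty stood at -2.25. These 3 of 4 sex chromosome genes passed when adjusted over the list alone, while Kdm5d (-0.17), also Y-linked, did not. The libraries did not follow their source in full. The mean CPM of Ddx3y, Eif2s3y and Uty was 25.6 to 73.8 in 8 ESC libraries and 0.9 in the library labelled ESC day 18 replicate 1. It was 0.6 to 1.5 in 5 iPSC libraries, 42.2 in the library labelled iPSC day 18 replicate 2 and 11.5 in iPSC day 25 replicate 1. Without the first and second of these 3 libraries, 3 genes were called, namely Eif2s3y (-5.36), Ddx3y (-4.20) and Uty (-3.13), the same genes by which those libraries were chosen, so this is no independent result. Of 21 imprinted genes none was called. The values were negative for Igf2 (-0.76), Dlk1 (-1.31), Rtl1 (-0.22), Peg10 (-0.55), Cdkn1c (-0.66), Snrpn (-0.51), Ndn (-0.72), Magel2 (-0.57), Mkrn3 (-0.25), Nnat (-0.17), Plagl1 (-0.41), Igf2r (-0.19) and Nap1l5 (-0.54). They were positive for Peg3 (0.18), Zim1 (0.08), Usp29 (0.14), Sgce (0.07), Mest (0.09), Grb10 (0.02), Zrsr1 (0.20) and Impact (0.11). Camera called 19 lists with the preset correlation and none with an estimated correlation (smallest adjusted p = 0.52), and fry called none. The preset count was 5 without ESC or iPSC day 35, and 11 without ESC day 18 replicate 1, iPSC day 18 replicate 2, or ESC or iPSC day 28.

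For the difference between sources in the change per day, no gene was called by limma (1233 at an unadjusted p under 0.05) or edgeR (970), while DESeq2 called 50. A difference that did not pass is not excluded. Camera called 10 lists with the preset correlation and none with an estimated correlation. The slope difference, iPSC minus ESC, was 0.08 log2 per day for Nrl. For the Müller glia list, fry gave an adjusted p of 0.026 with a median difference of -0.16 per day, and camera 3.5e-07 with the preset and an adjusted p = 0.17 with an estimated correlation. None of its 14 genes was called over all genes and 5 were lower adjusted over the list alone, and its most abundant members were Dkk3 (-0.30) and Acsl3 (-0.08). Other cell type lists had like medians, bipolar -0.15 (12 of 12 genes negative), amacrine -0.15 and retinal progenitor -0.14, with adjusted p = 0.087, 0.087 and 0.47 by fry and 0.37, 0.37 and 0.70 by camera with an estimated correlation. In tests chosen after seeing the data, fry's adjusted p for the Müller glia list was 0.65 without ESC day 35 (median -0.09), 0.27 without iPSC day 35, and 0.073 and 0.086 without iPSC day 18 replicates 1 and 2. Without ESC day 35 the bipolar median was 0.00, while fry called the amacrine list without ESC day 18 replicate 1 (0.037) or 3 (0.045) and the bipolar list without ESC day 28 (0.049). Camera with an estimated correlation called none of these, with adjusted p = 0.55, 0.18 and 0.27.

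The changes from day 18 to the mean of days 28 and 35 in ESC and iPSC, which share no library, correlated across 15202 genes at r = 0.616 (Spearman 0.569), with 69.4% of genes of the same sign. Genes are not independent replicates, so no p is given. The value was 0.388 without the low-Nrl pair, 0.4 with day 35 alone, 0.439 without ESC day 28, 0.477 without ESC day 18 replicate 1 and 0.482 without iPSC day 18 replicate 1. The day 18 mean of each source included 1 library of that pair, whose levels correlated with each other at 0.992. The changes of both sources may therefore not be independent.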

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

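All tests of explanations in this part were chosen after the values were seen.

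Of 60 sets of library values tested for an outlying library, 15 had one, where chance gives about 1 in 20. At day 21, ESC day 21 replicate 3 stood above the others in Nrl (1915.22 CPM), Nr2e3 (1675.06 CPM) and Prph2 (1209.87 CPM). Among ESC libraries, ESC day 35 was high in Gnat1 (139.38 CPM), and ESC day 18 replicate 1 was low in Crx (191.56 CPM) and Prph2 (8.05 CPM). Among iPSC libraries, iPSC day 18 replicate 1 was low in Nrl (15.99 CPM), Crx (197.75 CPM), Nr2e3 (8.65 CPM), Pde6b (0.92 CPM), Sag (9.05 CPM) and Prph2 (7.97 CPM). Source groups span all days, so a day effect alone can set a library apart there.

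The pair of day 18 libraries low in Nrl, labelled as of different sources, stood closer to each other (r = 0.992) than to their own groups. A repeated deposit of the same library is argued against by a chi-square of 8.7 per degree of freedom, where sampling noise gives about 1, but separate libraries of the same RNA or culture are not. Shallow sequencing is argued against by totals of at least 11190001 estimated counts, above the median of 5450037 in the other day 18 libraries. Cycling progenitor cells in the sorted sample stay a candidate explanation: both libraries exceeded each other day 18 library in the cell cycle list (by at least 1.04 log2) and the progenitor list (by at least 0.4). The sort aimed at GFP-positive cells, but its purity was not measured here. Other lists were highest in this pair at day 18 too, such as forebrain (mean log2 levels 4.21 and 4.27, against 1.8 to 3.6). An earlier stage of those cultures could give the same cell cycle and progenitor levels and was not tested.

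In the library labelled ESC day 18 replicate 1, Ddx3y (0.24 CPM), Eif2s3y (0.7 CPM) and Uty (1.84 CPM) were low, unlike in the other ESC libraries. Exchanged labels of this library and iPSC day 18 replicate 2 may account for it, since the partner, at a mean of 42.2 CPM, lay in the range of the ESC libraries, and both low-Nrl libraries would then be iPSC. Over all genes, ESC day 18 replicate 1 correlated at 0.992 with iPSC day 18 replicate 1 and at 0.949 and 0.896 with its own group, while the partner correlated at 0.943 and 0.906 with ESC day 18 replicates 3 and 2 and at 0.923 with its own group, which does not decide. The labels speak of clones without assigning them, so clones of different sex within a source cannot be told apart from this, and 3 libraries lay on the other side of 10 CPM from their source. In iPSC day 25 replicate 1 the ratios to the median ESC library were 0.32, 0.22 and 0.36, within 1.66-fold of each other, as a mixture of RNA from Y-positive and Y-negative cells may give.

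The Müller glia list differed between sources in its change per day (fry, adjusted p = 0.026), with an adjusted p = 0.17 by camera with an estimated correlation and 0.098 by fry with the replicate number as a block, and fry gave 0.65 without ESC day 35. In ESC day 35, 12 of its 14 genes were higher than in each other library, and the mean log2 levels of the bipolar list (4.97, next 3.15), the retinal pigment epithelium list (4.27, next 3.45) and the amacrine list (4.43, next 3.99) were highest there too. Levels there were 295.3 CPM for Apoe, 281.85 CPM for Vim, 250.6 CPM for Acsl3 and 241.2 CPM for Slc1a3, against 56.65, 19.71, 211.48 and 8.11 CPM in iPSC day 35. Cells of another type in the sorted sample may account for this, although the sort aimed at GFP-positive cells. The purity of the sort was not measured here. A longer culture in both sources stays open: 3 of the 14 genes in iPSC day 35 exceeded every day 18 library, and 1 library per source cannot decide.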

How the results depend on the processing

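The settings without 2 libraries, the rescaled CPM and the array weights were chosen after seeing the data, and all others before.

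Counts of called genes moved with many settings. No gene called by limma at days 25, 28 or 35 changed sign under any setting that tested it. Those genes were picked for their changes in the same libraries, so kept signs were likely in advance and are no independent support. For day 35 versus day 18 (1144), edgeR on gene sums called 643, with RLE size factors 682, limma with no filter 735, within ESC 115 and within iPSC 76, without the low-Nrl pair 147, without the Y-linked pair 632, and with array weights 292. For day 28 versus day 18 (88) these were 37, 36, 58, 1, 0, 1, 67 and 5687 (the 1 within ESC was Tma7-ps and the 1 without the low-Nrl pair Pde6a), with 593 by DESeq2 and 37 on length-scaled counts. For day 25 versus day 18 (6), RLE gave 24, DESeq2 974, length-scaled counts 0, no filter 2 (Gm13857 and Gm3972), within ESC 0 and within iPSC 0, without the low-Nrl pair 0, without the Y-linked pair 110, rescaled CPM 10 and array weights 9552. For day 21 versus day 18 (0), DESeq2 gave 107, no filter 1 (Gm3972) and array weights 6037. For ESC day 21 (0), DESeq2 gave 2 and no filter 1 (Gm3972), for iPSC versus ESC (0) a pseudocount of 0.1 gave 1 (Gm12751) and the fit without the Y-linked pair 3, and for the slope (0) DESeq2 gave 50. Array weights put 13.56 on ESC day 18 replicate 1 and 6.11 on iPSC day 18 replicate 1, the pair most alike, and at most 3.07 on any other library at day 21. In simulated data for day 35, DESeq2 called 56 unchanged genes, against 3 by limma. DESeq2 also recovered 29% of genes changed 2-fold and 77% of those changed 4-fold, against 11% and 52% by limma. Days 25 and 28 were not simulated. In the real day 35 comparison, DESeq2 kept 669 of the 698 limma calls it tested, and 49.4% of its own calls were higher. Rescaling moved the median of all genes at day 35 from 0.045 to -0.084 and gave 617 higher and 602 lower, against 690 and 454. A library left out leaves some groups with 1 sample, which is then assumed to vary like the others. The causes of these moves were not tested. These genes, where outside the rule, were named after their values were seen.

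The replicate block gave 1442 genes for day 25 versus day 18, 2003 for day 28 versus day 18 and 2614 for day 35 versus day 18, and 0 for each other comparison. Every library of days 28 and 35, and ESC day 25, is numbered 1. The block therefore set them mainly against the day 18 libraries numbered 1, which are the low-Nrl pair. The larger counts cannot be read apart from that pair. With the block, fry called 6 lists at day 25, 10 at day 28, 13 at day 35 and 0 for the slope. Without it, these counts were 3, 1, 9 and 1. The samples share only a number: deviations of same-numbered ESC libraries at days 18 and 21 correlated at 0.31, 0.06 and 0.25, and of iPSC libraries at days 18 and 25 at 0.38, a single value because 2 libraries per day mirror each other. Not every ESC library correlated best with its own number.

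Leaving out each library gave 0 to 249 genes at day 21, 0 to 1005 at day 25, 1 to 539 at day 28, 295 to 1808 at day 35, 0 to 2 for ESC day 21, and 0 for iPSC against ESC and the slope. Called lists ranged from 9 to 16 for ESC day 21 and 5 to 19 for iPSC against ESC, and the correlation of changes from 0.439 to 0.655.

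With an estimated correlation 0 lists were called in each comparison. Fry called 0 at day 21, 3 at day 25, 1 at day 28, 9 at day 35, 0 for ESC day 21, 0 for iPSC against ESC and 1 for the slope. For ESC day 21 (16 lists), 10 were called without the low-Nrl pair and 10 without the Y-linked pair, for iPSC against ESC (19) 10 on gene sums and 10 without the Y-linked pair, and for the slope (10) 16 without the Y-linked pair. The correlation was 0.4 at day 35 alone, 0.388 without the low-Nrl pair and 0.497 without the Y-linked pair.

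Of 3805 values of named genes under another setting, 3138 kept direction and side of the threshold, 549 lost the call, 40 gained it and 78 reversed. At day 35, Opn1sw was 0.10 with array weights, and Arr3 was -0.30 and -0.10 without the low-Nrl and the Y-linked pair (libraries left out, -0.34 to 1.01).

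For iPSC against ESC without the Y-linked pair, Nrl was -0.53, Crx -0.28, Nr2e3 -0.49, Pde6b -0.81, Prph2 -0.53, Arr3 -0.03 and Nnat 0.02. With the replicate block, Sag was 0.20, Opn1sw 0.11, Zim1 -0.08 and Mest -0.14. Without the low-Nrl pair, Sag was 0.16 and Grb10 -0.07. With array weights, Sag was 0.07, Kdm5d 0.02, Nnat 0.01, Grb10 -0.22 and Nap1l5 0.20. Rescaled, Arr3 was -0.01, Sgce -0.01 and Grb10 -0.06. By edgeR with TMM, with RLE, by DESeq2 and on length-scaled counts, Arr3 was -0.17, -0.17, -0.18 and -0.10, Mest -0.11, -0.12, -0.12 and -0.03, and Grb10 0, -0.01, 0 and -0.01. With each library left out, the ranges were -0.35 to 1.00 for Nrl, -0.16 to 0.58 for Crx, -0.30 to 1.17 for Nr2e3, -0.53 to 1.11 for Pde6b, -0.71 to 0.49 for Sag, -0.32 to 0.92 for Prph2, -0.92 to 0.22 for Opn1sw, -0.21 to 0.33 for Arr3, -0.39 to 0.02 for Gnat2, -0.40 to 0.04 for Kdm5d, -0.09 to 0.24 for Zim1, -0.17 to 0.29 for Mest, -0.40 to 0.02 for Nnat, -0.20 to 0.29 for Grb10 and -0.91 to 0.14 for Nap1l5.

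For the slope, Nrl was -0.11 with array weights (libraries left out, -0.16 to 0.24). None of these reversed values was called by limma over all libraries. Depth limits genes near the level of 3 counts, which was 0.111 to 0.639 CPM.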

Other observations

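Contrasts in this part were added after the data were seen, and so were the tests of other splits of the samples.

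The cone genes Opn1sw and Pde6c had their highest day means at days 25 and 21. Opn1sw, the short-wavelength opsin, averaged 31.75 CPM at day 18, 167.7 at day 21, 200.6 at day 25, 66.25 at day 28 and 3.645 at day 35, and its fall from day 25 to day 35 (log2 -5.49, SE 1.26) had an adjusted p of 0.12. The cone phosphodiesterase Pde6c averaged 99.5 CPM at day 21 and 2.48 at day 35. Of the cone list, 1 of 14 genes, Pde6c, was called at day 35 against day 18 (camera, adjusted p = 0.26, and 0.00037 without the low-Nrl pair; fry, 0.58). With an estimated correlation and all libraries, camera gave an adjusted p of 0.83. From day 25 to day 35, 10 genes were called by limma, 6 higher and 4 lower. Gnat1 (3.68), Pde6a (3.76) and the nuclear receptor Esrrb (3.95) rose, and Cyp26b1 (-5.54), Islr2 (-4.44) and Onecut1 (-3.84) fell.

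A linear trend with day over all 16 libraries called 1840 genes, 1036 higher and 804 lower, and 798 without the low-Nrl pair. Pde6a changed most firmly (0.41 log2 per day, adjusted p = 2.58e-07).

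Other splits of the same libraries into groups of the same sizes were fitted. For day 25 against day 18, 4 of 56 splits gave at least the 6 genes of the real one and the highest other gave 675, so chance is not excluded. Its libraries were ESC day 18 replicates 1 and 3 and iPSC day 18 replicate 1 against the rest, which points to a structure of the samples. Where the real split gave 0 genes, every split is as large by construction, which says nothing about chance: 100 of 100 for day 21 against day 18 (highest other 1572), the source contrast (highest other 4) and the slope (highest other 1760). Splits with that many calls point to a structure of the samples: the highest at day 21 set ESC day 21 replicates 2 and 3, iPSC day 18 replicate 2 and iPSC day 21 (-56 to 2.1 on the first principal component) against the other 5 libraries (42.7 to 91.7). That of the slope took ESC day 21 replicate 3, ESC day 28 and ESC day 35 as iPSC. Beside them it kept iPSC day 18 replicate 2, iPSC day 21, iPSC day 25 replicate 2 and iPSC day 28, with all other libraries as ESC. The 10 splits of ESC day 21 and day 18 are too few for a share under 0.05, with 0 genes in the real split, 10 of 10 as large and 1 in the highest other.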
